A study of Mus musculus with 6 samples.

How the data were processed

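Gene expression was measured by RNA sequencing of poly(A)-selected RNA from E14 mouse embryonic stem cells, in 3 libraries without doxycycline and with wild-type Nat10 (CON) and 3 with doxycycline and the Nat10 knockdown (KD). Per the submitters' processing notes, the tools FastQC 0.11.9, STAR 2.5.3a and featureCounts and the genome build mm10 were used. Per the labels' design text, a paired-end cluster kit was used on an Illumina HiSeq. The annotation release, the strand setting and the treatment of multi-mapping reads are not given in the sources used here.

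The table deposited by the authors holds raw counts of reads per gene, per the file headers, for 31641 genes, each with at least 1 count in some library. It also holds FPKM values that the authors made by scaling those counts by gene length and library total, which were checked against the counts and used for nothing else. The deposited table further gives the authors' own log2 fold change and adjusted p-value per gene, whose test is not given in the sources used here. From the values, the authors' log2 fold change is CON over KD. Columns were matched to samples by the treatment and number in their names, and none was left unmatched. Dates had replaced 26 gene symbols in the table, and all 26 were restored from the gene identifier. Of the identifiers, 31521 (99.6%) were found in GENCODE M21, which gave positions on GRCm38. Where 34 rows shared a symbol, the row with most reads kept it.

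Of deposited counts from 1 to 20, between 70 and 71.7% were even in each library. Counts of independent reads would be even and odd about as often, and counting both mates of a pair as separate reads gives such an excess. Low counts then stand for fewer fragments than their value, and the counting error behind them is larger than the value shows. As an alternative chosen after seeing the data, the fits were repeated on counts divided by 2.

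Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups (18019 genes), libraries were scaled by TMM, with factors from 0.922 to 0.926 in CON and from 1.08 to 1.084 in KD, and KD was compared with CON by the robust quasi-likelihood F-test. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of F. CPM values use the TMM-scaled library sizes. The 10 most abundant genes held 4.92 to 4.99% of counts in CON and 4.19 to 4.34% in KD. A single count was worth 0.0253 to 0.0296 CPM, before TMM scaling.

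The comparison, its test, the 24 gene lists (853 entries) and the alternatives were fixed before the data were examined. Lists were tested against all other genes with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation. The fry test of limma, which asks whether a list moves 1 way on balance, was run beside it. Some genes are in more than 1 list, among them Nanog, Trim28 and Lin28a. Another 7 lists were chosen after the data were examined and are adjusted among themselves. With the preset correlation, camera also called 9 to 13 lists in the other splits of the 6 libraries, and with the estimated correlation it called 0 there and 6 lists in the real comparison. The 6 are the naive, core, 2C regulator, integrated stress, ribosomal protein and cholesterol lists. Each of the other splits mixes CON and KD libraries unequally. It keeps part of the real difference between its groups and adds the rest to the spread within them. Its counts therefore do not show how often unchanged lists are called. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the number of genes, which alone raises p. The estimates for the unfolded protein, interferon and fatty acid lists were -0.011, -0.014 and -0.052, below the preset 0.01. The lost calls of these lists therefore do not come from correlation between members.

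Genes were named by a rule fixed at the same time. It takes Nat10, then the 12 largest rises and falls among genes that pass, have a mean of at least 1 CPM and show no overlap between groups. It adds up to 4 members per direction of each list by smallest p, the 6 genes per direction with the smallest p at 50 CPM or more, and a fixed set of pluripotency, 2C and lineage genes. Gene-model names were counted but not named, which passed over 1 gene among the rises. Some genes that the rule takes are not reported here. Rest, Atf4, Myc and Rcor2 and the examples from the 7 later lists were chosen after their values were seen.

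Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Among named genes this concerns Pou5f1 (317 exonic bases shared with Gm19553), Syp (875 with Gm14703), Aldh1l2 (1056 with D10Wsu102e), Fn1 (292), Cdkn1a (273), Lin28a (234), Hk1 (157), Otx2 (154), Map2 (124), Tbx3 (115), Gata6 (93), Stat3 (72), Rpl12 (56), Rps2 (14) and mt-Co1 (3). Among genes named from the later lists it concerns Chrnb2 (1365 with Adar), Srebf1 (109) and Elovl6 (34). Single copies of the Zscan4, Usp17l and Pramef families and ribosomal protein genes with pseudogenes are uncertain where reads were shared.

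The fits were tested on simulated data. In the simulated KD against CON comparison of 17712 genes, edgeR recovered 56.4% of genes changed by 0.5, 77.9% of those changed by 1 and 95.8% of those changed by 2 on the log2 scale, with 6 false calls. Only 55, 68 and 72 genes were changed by these sizes, so the simulation does not show the error where most genes change. In simulated lists, 0 of 23 unchanged lists were called. Counts were drawn for each gene independently, so the simulated lists hold no correlation between genes and cannot test the preset value. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, leaving out each replicate, a replicate block, a threshold of 0.01 and, added later, the removal of GC and length trends. The removal was tested on a simulated GC trend over 17648 genes, where it took 9136 calls to 0. No gene was changed in that simulation, so it does not show whether the removal keeps real changes. The trends were fitted to deviations from the mean of all 6 libraries. A real difference between the groups that follows GC content or length would thus be removed too.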

Results

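Messenger RNA was sequenced from E14 cells, a line of mouse embryonic stem cells, in 6 libraries. Per the labels, 3 control libraries (CON) came from cells with wild-type Nat10 and no doxycycline, and 3 knockdown libraries (KD) from cells given doxycycline to lower Nat10. Nat10 is an RNA acetyltransferase, and the series title asks what it does for pluripotency and for the 2C state, in which cultured stem cells express genes of the 2-cell embryo. All KD libraries received doxycycline and no CON library did, so the drug and the knockdown share every difference given here. The libraries held 36808429, 39450202 and 35304394 counts for CON-1, CON-2 and CON-3, and 38859069, 39524273 and 33770755 for KD-1, KD-2 and KD-3. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Levels below are TMM-scaled CPM, the share of a library's counts on a common scale, as mean ± SD with n = 3 libraries per group, and fold changes are KD over CON with their standard error (SE).

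Nat10 itself was lower in every KD library. Its raw counts were 4960, 5496 and 4877 in CON-1, CON-2 and CON-3, against 1100, 1164 and 1050 in KD-1, KD-2 and KD-3. The mean fell from 149 ± 2.93 to 27.4 ± 1.24 CPM, a 5.44-fold lower level (log2 fold change -2.44, SE 0.054, edgeR adjusted p = 4.21e-14). The gene lies on chromosome 2 from 103721256 to 103761270 on the reverse strand (GRCm38, GENCODE M21). Thumpd1, an RNA-binding adaptor of Nat10, fell 1.61-fold, from 123 ± 3.32 to 76.3 ± 3.92 CPM (edgeR adjusted p = 1.54e-08).

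Pluripotency genes fell together in KD. Of 31 naive pluripotency genes, 26 fell, 3 rose and 2 did not pass the test, with a median log2 fold change of -1.52. Of 22 core pluripotency genes, 20 fell and 2 rose, with a median of -1.51. Pou5f1, which encodes OCT4, fell 3.19-fold from 732 ± 21.5 to 229 ± 21.3 CPM, and its partner Sox2 fell 3-fold from 507 ± 10.7 to 169 ± 16.2 CPM. Nanog fell 3.02-fold from 639 ± 22.8 to 212 ± 1.79 CPM. The naive-state transcription factors Klf4, Klf5 and Esrrb fell 3.79-fold, 5.09-fold and 2.42-fold, and Zfp42, the marker also called Rex1, fell 4.2-fold from 757 ± 3.03 to 180 ± 11.1 CPM. The members that rose were Mael (1.64-fold), Stat3 (1.19-fold) and Dppa3 (1.79-fold) in the naive list, and Lin28b (1.52-fold) and Epcam (1.2-fold) in the core list. The same numbers passed when p-values were adjusted over the list alone. Against all other genes, limma's camera test gave adjusted p = 7.52e-10 for the naive list and 2.07e-08 for the core list, and adjusted p = 0.022 and 0.0248 with an estimated correlation.

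Genes of formative and primed pluripotency, which mark the step that follows the naive state, mostly fell as well. Of 24 tested, 14 fell, 4 rose and 6 did not pass, and adjusted over the list alone 15 fell and 4 rose. Otx2, a transcription factor of that step, fell 5.6-fold from 75.6 ± 1.49 to 13.5 ± 0.726 CPM, and the DNA methyltransferase gene Dnmt3b fell 2.13-fold. Cdh2, which encodes N-cadherin, rose 3.44-fold from 4.88 ± 0.393 to 16.8 ± 0.798 CPM. The list's camera call (adjusted p = 0.00332) was lost, at adjusted p = 0.411 with an estimated correlation. Fgf5, a common primed marker, had too few counts to be tested, with 8, 2 and 2 in the CON libraries and 4, 4 and 4 in the KD libraries.

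**Figure D1:**
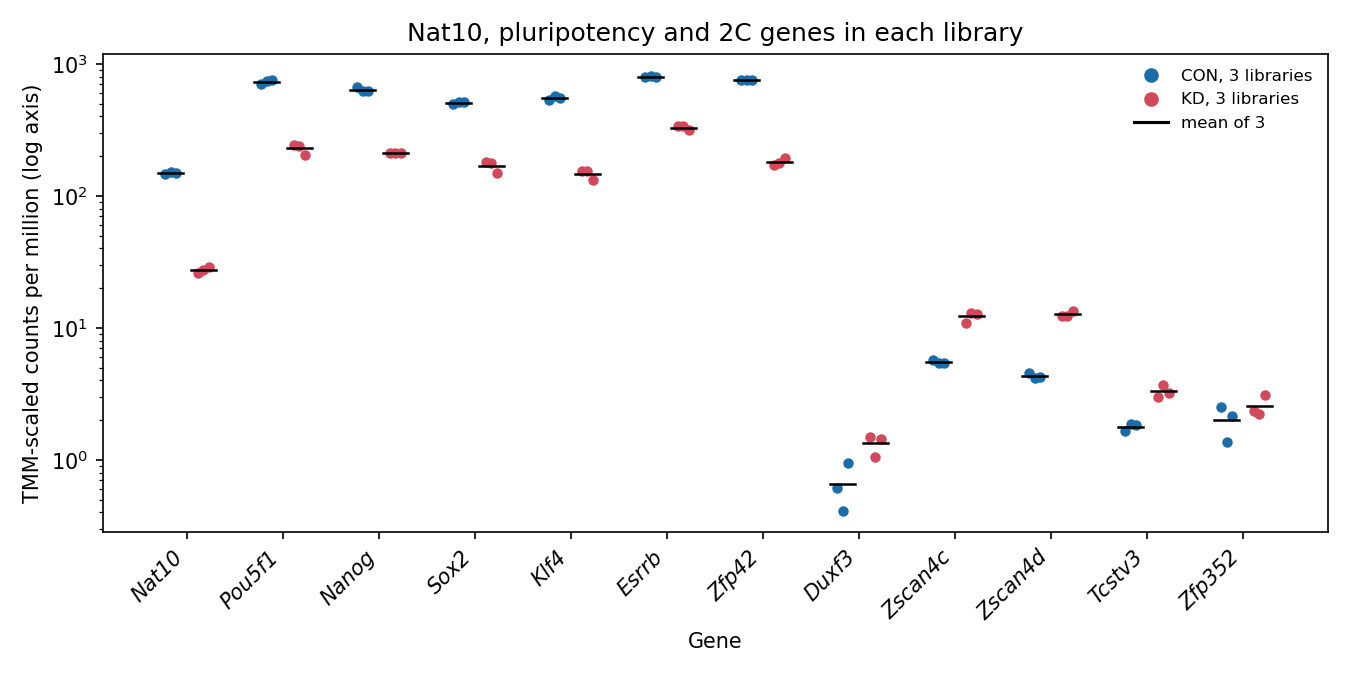
Level of Nat10, of 6 pluripotency genes and of 5 genes of the 2C state in each library, as TMM-scaled CPM on a log axis, with CON libraries in blue, KD libraries in red and a black bar for the mean of 3. Nat10 falls from a mean of 149 to 27.4 and Pou5f1 from 732 to 229, while Zscan4d rises from 4.34 to 12.7 and the Zfp352 values of the groups overlap.

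Members of the 2C list moved in both directions. Of 50 tested 2C genes, 19 rose, 9 fell and 22 did not pass, over all genes and adjusted over the list alone, with a median log2 fold change of 0.32. With libraries scaled by size only, 26 rose, 6 fell and the median was 0.55. Zscan4d, of the Zscan4 cluster that marks 2C-like cells, rose 2.92-fold from 4.34 ± 0.208 to 12.7 ± 0.739 CPM, and its neighbour Zscan4c rose 2.21-fold from 5.52 ± 0.182 to 12.2 ± 1.1 CPM. Tcstv3 rose 1.85-fold and Tmem92 3.77-fold. Duxf3, the mouse Dux gene that drives the 2C program, rose 2.03-fold from 0.661 ± 0.273 to 1.33 ± 0.247 CPM (edgeR adjusted p = 0.0133). It rested on 21, 15 and 31 counts in CON and 63, 45 and 53 in KD, and without CON replicate 2 its adjusted p was 0.0648 in edgeR. Zfp352 did not pass, at 2.02 ± 0.586 CPM in CON and 2.57 ± 0.479 in KD (edgeR adjusted p = 0.207). Tcstv1 had too few counts to be tested, with 0 in each CON library and 1, 0 and 3 in the KD libraries. Of the list's PRAME family, Pramel7 and Pramel6 fell 7.79-fold and 13.3-fold, from CON levels of only 2.32 ± 0.387 and 0.811 ± 0.176 CPM. The more abundant Pramef12 rose 1.41-fold, from 90.9 ± 1.05 to 128 ± 6.81 CPM.

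As a set, the 2C list did not pass limma's camera test (adjusted p = 0.108, and adjusted p = 0.539 with an estimated correlation). It passed with fry, also from limma, which asks only whether its genes move 1 way on balance (adjusted p = 0.00251). Of the 24 fixed lists, however, 23 passed fry, all but the mitochondrially encoded one (adjusted p = 0.059). It passed camera with no count filter (adjusted p = 0.0455), with at least 1 CPM in 3 libraries (0.0228) and with GC and length trends removed (0.0314). Zscan4c lies on chromosome 7 from 11005745 to 11010547 and Zscan4d from 11161374 to 11166159 (GRCm38). The copies of this cluster are related genes, as are those of the Usp17l and Pramef families in the list, and their sequences were not compared here. The level of each single copy is uncertain where reads were shared between them.

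Known regulators of the 2C state, most of which hold it in check, fell as a group. Of 44 tested, 35 fell, 3 rose and 6 did not pass, with a median log2 fold change of -0.58. With libraries scaled by size only, 24 fell, 8 rose and the median was -0.35. Trim28, a corepressor of endogenous retroviruses, fell 2.31-fold from 2120 ± 62.3 to 917 ± 43.4 CPM, and the RNA-binding protein gene Lin28a fell 2.84-fold. Nr5a2 fell 3.15-fold and Tbx3 2.8-fold, and these 2 genes are also in the naive list. The regulator list was not split into genes that hold the 2C state in check and genes that promote it. These falls therefore need not all be of genes that hold it in check. Trim28 and Lin28a are also in the core list, so the fall of the regulators is in part that of the pluripotency lists. Smarca5, a chromatin remodeller, had 224 ± 9.64 CPM in CON and 215 ± 9.22 in KD and did not pass (edgeR adjusted p = 0.303). It was higher, not lower, when libraries were scaled by size only (log2 fold change 0.17). The list passed camera at adjusted p = 1.78e-08 in limma, and at adjusted p = 0.0412 with an estimated correlation.

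Every one of the 39 tested genes of the ATF4 pathway, also called the integrated stress response, was lower in KD. This list had the largest shift of the 24 fixed lists, with a median log2 fold change of -1.95. Mthfd2, an enzyme of mitochondrial folate metabolism, fell 7.87-fold from 416 ± 3.82 to 52.9 ± 2.27 CPM. Chac1, which degrades glutathione, fell 38.7-fold from 133 ± 4.98 to 3.44 ± 0.761 CPM. The serine synthesis gene Psat1 fell 5.08-fold, the cysteine synthesis gene Cth 7.94-fold, the cationic amino acid transporter gene Slc7a3 6.61-fold and the pseudokinase gene Trib3 8.73-fold. The list passed limma's camera test at adjusted p = 4.59e-20, and at adjusted p = 0.022 with an estimated correlation. Scaled by library size only, its median was -1.72 and 38 of its genes fell.

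Of 26 genes of the endoplasmic reticulum's unfolded protein response, 18 rose, 3 fell and 5 did not pass, with a median log2 fold change of 0.35, or 0.58 with libraries scaled by size only. Hspa5, which encodes the chaperone BiP, rose 1.67-fold from 307 ± 3.49 to 513 ± 24 CPM, and Calr rose 1.43-fold. Herpud1, which acts in protein degradation at the endoplasmic reticulum, fell 4.43-fold, and the stress sensor gene Atf6 1.2-fold. The list's camera call in limma (adjusted p = 0.0124) was lost, at adjusted p = 0.109 with an estimated correlation. The estimate itself was -0.011, below the preset 0.01, so correlation between members is not the reason.

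The 12 largest falls with a mean of at least 1 CPM were led by Fgf21, Hrk, Chac1, Nupr1 and Inhbe. Fgf21, a secreted stress hormone, fell 52.6-fold from 2.77 ± 0.51 to 0.0494 ± 0.0469 CPM, with 0, 4 and 2 counts in the KD libraries. Hrk, a pro-apoptotic BCL2-family gene, fell 40.7-fold from 21.6 ± 0.931 to 0.528 ± 0.0167 CPM. Further falls among them were Ubap1l, Adgrd1, Fut1, Slc7a11, Aldh1l2 and Creb5, from 22.6-fold for Ubap1l to 12.3-fold for Creb5.

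The 12 largest rises of genes with a mean of at least 1 CPM included Syp, Scg3, Drd2, Scrt1, Actl6b and Gdap1. Syp, which encodes the synaptic vesicle protein synaptophysin, rose 32.1-fold from 0.904 ± 0.0816 to 29.1 ± 0.828 CPM. Scg3, a secretory granule gene, rose 28.5-fold from 0.695 ± 0.114 to 20 ± 2.73 CPM. The dopamine receptor gene Drd2, the transcription factor gene Scrt1 and the neuronal chromatin subunit gene Actl6b rose 54.4-fold, 49.6-fold and 37.3-fold. Gdap1 had the largest rise, 60.5-fold to 6.08 ± 1.38 CPM. Its CON libraries held 6, 4 and 0 counts and those of Drd2 4, 4 and 0. For Scrt1 they held 4, 5 and 0 counts and for Actl6b 0, 2 and 6. The size of these folds thus rests on few reads. Masp1, Scg5, Kcnc1, Kcna5, Npas1 and Disp2 completed the 12. Among genes of at least 50 CPM, those with the smallest p that rose were Adgrg1 (5.79-fold), Madd, Tmem43, Vgf (4.44-fold), Gpx3 and Tcn2. Vgf encodes a neuropeptide precursor and rose from 30.8 ± 3.15 to 137 ± 10.8 CPM.

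Most growth and division genes fell. Of 79 cytosolic ribosomal protein genes, 78 fell and 1 did not pass, with a median log2 fold change of -0.51. Rps2 fell 1.6-fold from 4960 ± 105 to 3100 ± 87.1 CPM and Rpl12 fell 1.72-fold. The list passed limma's camera test at adjusted p = 2.06e-15, and at adjusted p = 0.0368 with an estimated correlation. Scaled by library size only, 63 fell, 1 rose and the median was -0.28. Many of these genes have processed pseudogenes, whose reads may be shared with them.

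Of 72 ribosome biogenesis factors, which make ribosomes in the nucleolus where Nat10 also acts, 64 fell, 2 rose and 6 did not pass. Tcof1, the rRNA transcription factor Ubtf and Nop58 fell 2.46-fold, 2.16-fold and 2.52-fold, while Polr1e rose 1.3-fold. The camera call in limma (adjusted p = 1.59e-13) was lost, at adjusted p = 0.109 with an estimated correlation. Of 37 DNA replication genes, 31 fell, 2 rose and 4 did not pass. Mcm5, a subunit of the replicative helicase, fell 3.84-fold from 667 ± 28 to 174 ± 3.6 CPM. The camera call in limma (adjusted p = 2.07e-08) was lost, at adjusted p = 0.0582 with an estimated correlation. Of 30 mitotic genes, 29 fell and 1 did not pass, with Ccnb1, which encodes cyclin B1, falling 2.83-fold from 369 ± 3.81 to 130 ± 5.84 CPM. This call in limma (adjusted p = 1.17e-09) was lost as well, at adjusted p = 0.145 with an estimated correlation. With libraries scaled by size only, 49 ribosome biogenesis, 24 DNA replication and 24 mitotic genes fell, and 7, 6 and 1 rose. Adjusted over the list alone, the counts of these 4 growth lists were the same as over all genes.

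Cholesterol synthesis genes rose. Of 24 tested, 22 rose, 1 fell and 1 did not pass, with a median log2 fold change of 0.54. Dhcr7, a late enzyme of cholesterol synthesis, rose 2.82-fold from 37.8 ± 0.113 to 107 ± 5.31 CPM. The member that fell, the isomerase gene Ebp, did so by 1.14-fold (edgeR adjusted p = 0.0326), and it did not fall with libraries scaled by size only. The list passed limma's camera test at adjusted p = 4.05e-06, and at adjusted p = 0.0357 with an estimated correlation.

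Of 22 glycolysis genes 8 rose and 13 fell, and adjusted over the list alone 8 rose and 14 fell. The hexokinase genes moved apart, Hk1 rising 1.49-fold and Hk2 falling 2.06-fold, and the list did not pass camera (adjusted p = 0.191 in limma). Of 63 nuclear-encoded respiratory chain genes 14 rose and 23 fell (camera adjusted p = 0.335 in limma), with Uqcrh rising 2.33-fold and Atp5b falling 1.31-fold. The balance of that list turned with libraries scaled by size only, to 33 higher and 4 lower, and its median went from -0.07 to 0.16. Under the same scaling 10 glycolysis genes rose and 9 fell. Of 10 mitochondrially encoded genes 6 rose and 1 fell, with mt-Nd4 rising 1.6-fold and mt-Co1 falling 1.21-fold (camera adjusted p = 0.15 in limma). The share of counts on the mitochondrial genome ranged from 1 to 1.11% in CON and from 1.17 to 1.4% in KD. The mitochondrial list passed camera in limma without KD replicate 1 (adjusted p = 0.03), with no count filter (0.0391) and with GC and length trends removed (0.00556), but not with an estimated correlation (0.635).

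Of 36 p53 target genes 18 rose and 13 fell (camera adjusted p = 0.381 in limma), and with libraries scaled by size only 22 rose and 8 fell. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 1.87-fold from 58.6 ± 4.06 to 110 ± 6.35 CPM, and Ccng1 rose 1.67-fold. Gdf15 and Sesn2, which are also in the integrated stress list, fell 6.7-fold and 2.11-fold. Of 31 interferon-stimulated genes 20 rose and 6 fell, with a median log2 fold change of 0.52. The RNA sensor gene Ifih1 rose 9.69-fold, from 0.488 ± 0.341 to 4.75 ± 0.783 CPM, and Oasl2 rose 6.53-fold, while Xaf1 fell 3-fold. The camera call of that list in limma (adjusted p = 0.0235) was lost, at adjusted p = 0.109 with an estimated correlation, 0.155 with libraries scaled by size only and 0.0576 with at least 1 CPM in 3 libraries. Its estimated correlation was -0.014, below the preset 0.01.

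Genes of other lineages moved in both directions, and none of these lists passed camera in limma. Of 19 primitive streak and mesoderm genes 7 rose, 5 fell and 7 did not pass, and adjusted over the list alone 8 rose and 5 fell. Hand1 fell 5.79-fold and Wnt3 rose 2.58-fold, while T had 1.12 ± 0.308 CPM in CON and 0.893 ± 0.338 in KD and did not pass. The list's median was 0.36 but its mean was -0.05, its camera adjusted p was 0.869 and fry gave a fall at adjusted p = 0.0125. Its direction also turned, without passing, in 6 further alternatives. Of 24 endoderm genes 6 rose and 11 fell (camera adjusted p = 0.275). The basement membrane gene Lamb1 rose 1.67-fold and Apoe fell 2.75-fold, while Gata6 had 1.93 ± 0.445 CPM in CON and 1.62 ± 0.734 in KD and did not pass. Of 15 neuroectoderm genes 6 rose and 7 fell (camera adjusted p = 0.672), with Map2 rising 2.77-fold and Tubb3 falling 6.59-fold. Of 23 trophectoderm genes 8 rose and 9 fell (camera adjusted p = 0.7), with Cdx2 falling 1.63-fold and Cdh3 rising 1.5-fold. With libraries scaled by size only, 14 trophectoderm genes rose and 7 fell, and the median went from 0.02 to 0.25. The medians of the endoderm and neuroectoderm lists were -0.21 and -0.19, and 0.02 and 0.04 with libraries scaled by size only, when 6 endoderm genes rose and 8 fell and 6 neuroectoderm genes rose and 6 fell.

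Fibroblast markers, which feeder cells would bring, had 10 members higher and 5 lower among 18 (camera adjusted p = 0.0771, fry adjusted p = 0.000245, both from limma). They passed camera with limma-voom (adjusted p = 0.0467) and with no count filter (0.0378), but not with an estimated correlation (0.559). Col1a2 rose 10.8-fold from 1.53 ± 0.234 to 16.6 ± 1.68 CPM and Col6a1 8.97-fold, while Vim and Thy1 fell 1.71-fold and 2-fold. Fn1, by far the most abundant of those named, fell 1.48-fold from 2130 ± 45.8 to 1440 ± 24.9 CPM. Of 34 germline genes 22 rose and 9 fell, with the meiotic genes Rec8 and Sycp2 rising 4.97-fold and 5.23-fold and Ddx4 3.08-fold. The germline call in limma (camera adjusted p = 0.0401) was lost, at adjusted p = 0.559 with an estimated correlation. It was also lost with libraries scaled by size only (0.155) or by upper quartile (0.054), and without CON replicate 1 (0.0536), CON replicate 2 (0.0628) or KD replicate 3 (0.0575). Of 28 imprinted genes 7 rose and 12 fell, and adjusted over the list alone 8 rose and 12 fell (camera adjusted p = 0.381 in limma). Ndn rose 3.75-fold and Grb10 fell 4.08-fold. The imprinted list's median was -0.04, and 0.19 with libraries scaled by size only, when 13 rose and 9 fell. For the fixed lists not given an own count adjusted over the list alone, it was the same as over all genes.

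**Figure D2:**
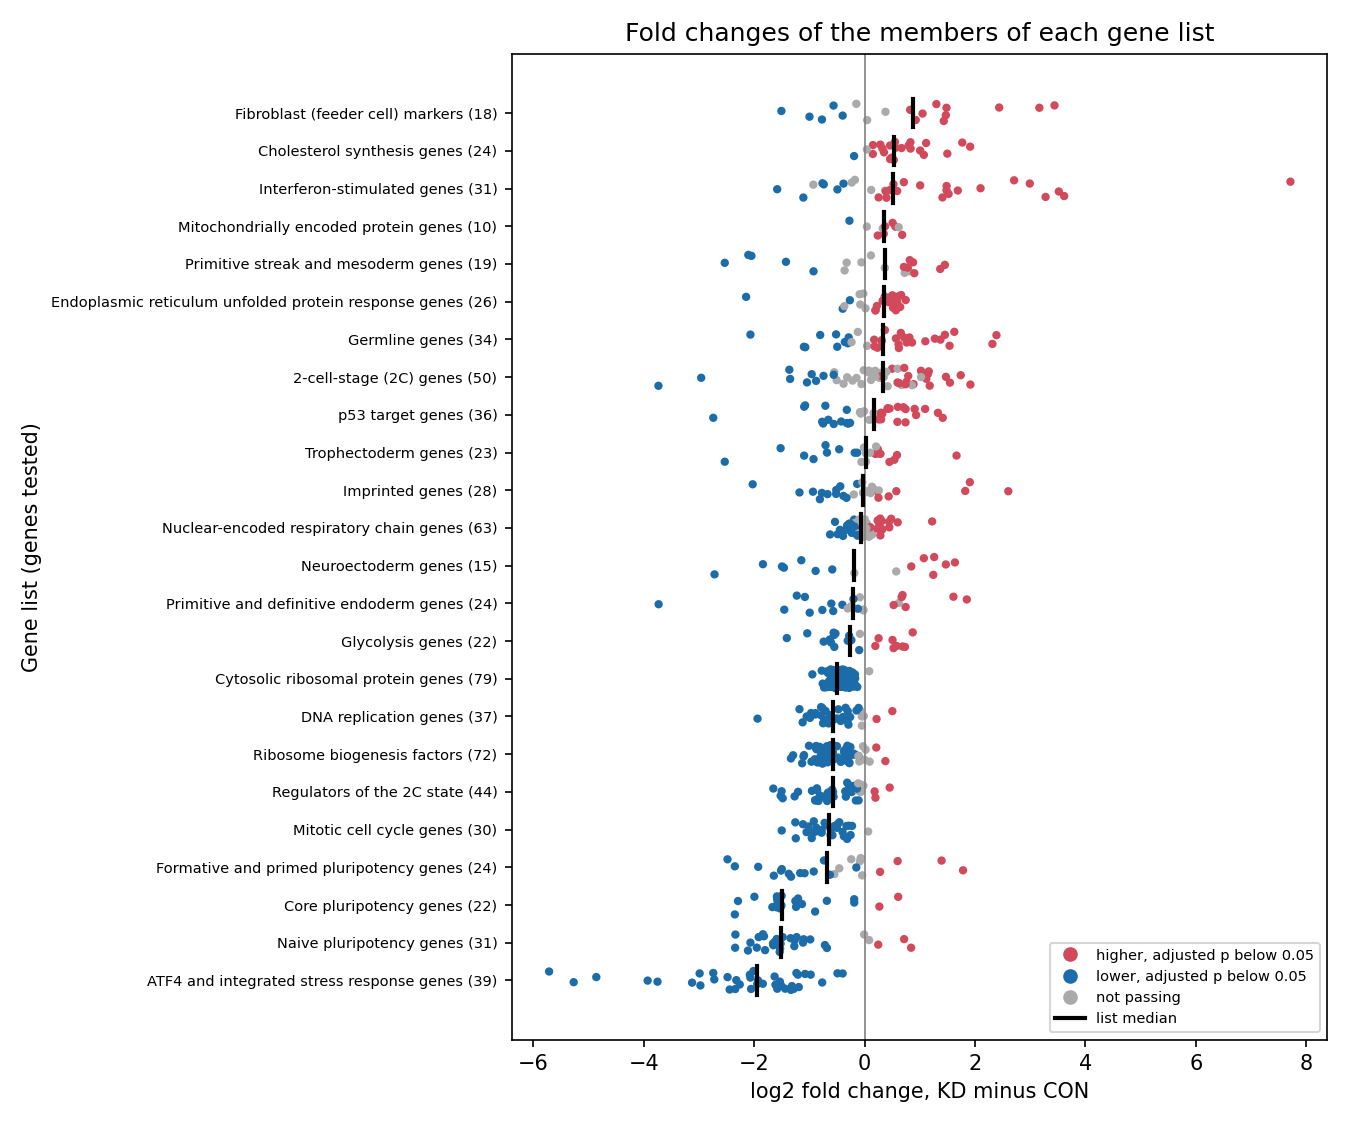
Log2 fold change (KD minus CON) of each tested member of the 24 fixed gene lists, ordered by list median, with the number of genes tested in brackets. Red points passed higher and blue points lower by edgeR at an adjusted p below 0.05, grey points did not pass, and black bars are medians, from -1.95 for the ATF4 list to 0.87 for the fibroblast markers. The rightmost point is Ifit1, which had no count in any CON library, so its plotted fold depends on the prior count. Against 3 counts per library it was at least 7.96-fold higher. With libraries scaled by size only, the medians of the endoderm, neuroectoderm, respiratory chain and imprinted lists change sign.

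Across the transcriptome the change was broad. Of 18019 genes tested by edgeR, 5801 were higher and 5543 lower in KD at an adjusted p below 0.05, and 6675 did not pass. At 2-fold or more, 1754 were higher and 1281 lower. The 3 CON and 3 KD values did not overlap in 12097 genes (67.1%), where chance gives 10% for 3 against 3. The first principal component held 76.5% of the variance and separated the groups. With libraries scaled by size only, 8280 genes were higher and 3535 lower, so that 70.1% of calls were higher in place of 51.1%, and the median of all genes moved by 0.229 on the log2 scale. All changes above are therefore relative to the bulk of genes in the library.

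KD replicate 3 stood apart from the other KD libraries. Its counts differed from those of KD-1 and KD-2 with a chi-square per degree of freedom of 14.6 and 10.9, against 2.99 between KD-1 and KD-2 and 2.69 to 5.07 among the CON pairs. Halved for mates counted separately, the lowest of these values, between CON-2 and CON-3, was 1.34, where counting noise alone gives 1. Across genes, the deviation of KD-3 from the mean of its group correlated with GC content at -0.488 (Spearman). The values were 0.394 for KD-1 and 0.269 for KD-2, and -0.304, 0.216 and 0.135 for CON-1, CON-2 and CON-3. Whether GC content accounts for the difference of KD-3 was not tested. Without KD-3, 5944 genes were higher and 5862 lower.

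The authors' deposited table gives log2 fold changes in the opposite direction, CON over KD, with 2.45 for Nat10. Of the genes that the authors' deposited table calls lower in CON, 1559 were tested here, and all 1559 were past the threshold and at least 2-fold higher in KD. Of 1171 tested genes that the authors' deposited table calls higher in CON, 1155 were at least 2-fold lower in KD. The source counts are the same in both, so this compares methods, not experiments.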

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

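The alternatives that removed GC and length trends or used halved counts were chosen after seeing the data, and the others before the data were examined. The count of genes higher in KD stayed within 1.5 times its value in all of them, and that of genes lower in KD in all but 1, falling to 3535 with libraries scaled by size only. That setting leaves out the composition factors, which differ between the groups. Nat10 was lower under every alternative run on it. The naive and core lists passed under each one run on lists, and DESeq2 and the 0.01 threshold were not run on lists. The 2C list, not past the threshold at first (adjusted p = 0.108), passed with no count filter (0.0455), with at least 1 CPM in 3 libraries (0.0228), with fry (0.00251), which asks another question, and with GC and length trends removed (0.0314). Its adjusted p ranged from 0.00251 to 0.539 over the alternatives, and apart from fry the cause was not tested. With halved counts 5658 genes were higher and 5428 lower. The direction reversed for Ebp (log2 fold change 0.037) and Smarca5 (0.17) with libraries scaled by size only, and for the mesoderm list with fry (0.0125), whose mean and median differ in sign. The mesoderm direction also turned, without passing, in 6 further alternatives, and those of the trophectoderm and respiratory chain lists in 1 each. Named genes lost their call in 10 cases and gained it in 2, and the other lists lost it in 14 and gained it in 13. Smarca5 passed without KD replicate 3 (-0.1). No pairing by replicate number was seen: deviations of same-numbered libraries correlated at -0.061, 0.015 and -0.039. These values cannot exclude a shared culture or batch. The replicate block gave 5559 genes higher and 5347 lower and changed no call of a list. Few reads in a group limit the folds of Duxf3, Fgf21 and Gdap1, among others.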

Other observations

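The tests of scaling and of endoplasmic reticulum stress for the ATF4 list and the test of shared Zscan4 reads, the removal of GC and length trends, and the 7 lists of this part were chosen only after the results they bear on were seen. Among these lists, neuronal genes known as targets of the repressor REST had the smallest camera p. Of 47 tested, leaving out those already named, 34 rose, 5 fell and 8 did not pass, over all genes and adjusted over the list alone. Celsr3 rose 6.25-fold from 11.5 ± 0.706 to 72.1 ± 4.52 CPM, Chga, the granule protein chromogranin A, rose 4.09-fold and Chrnb2, a nicotinic receptor subunit, 6.05-fold, while Stmn2 fell 4.34-fold from 94.6 ± 1.97 to 21.8 ± 1.34 CPM. The list's camera call in limma (adjusted p = 2.16e-05) was lost, at adjusted p = 0.182 with an estimated correlation.

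Of 25 tested Hox genes 12 rose and 4 fell, with Hoxb4 rising 5.23-fold from 1.21 ± 0.286 to 6.32 ± 0.324 CPM and Hoxb9 falling 1.26-fold. The camera call in limma (adjusted p = 0.0461) was lost, at adjusted p = 0.309 with an estimated correlation. Of 18 fatty acid synthesis genes 11 rose and 3 fell, and adjusted over the list alone 12 rose and 3 fell. The regulator gene Srebf1 rose 2.21-fold from 85.6 ± 1.54 to 189 ± 23.7 CPM and Acly 1.58-fold, while Elovl6 fell 1.67-fold. This call in limma (adjusted p = 0.0395) was lost, at adjusted p = 0.182 with an estimated correlation. The estimate for the fatty acid list was -0.052, below the preset 0.01. Lysosomal genes (20 higher, 14 lower), hypoxia-inducible genes (10 higher, 10 lower), Wnt target genes (10 higher, 6 lower) and basement membrane genes (11 higher, 8 lower) did not pass camera in limma, at adjusted p = 0.265, 0.748, 0.342 and 0.493. Adjusted over the list alone, 11 Wnt target genes were higher and 6 lower, and the counts of the Hox, lysosomal, hypoxia and basement membrane lists were the same as over all genes.

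Syp, Scg3, Drd2 and other genes known from neurons were among the largest rises, and relief from the repressor REST may contribute. These genes were picked from the rises, not from a fixed list. The fixed neuroectoderm list moved both ways, with 6 genes higher and 7 lower (camera adjusted p = 0.672 in limma). The other REST targets had a median log2 fold change of 0.79, and Rest mRNA itself changed by -1.93 (SE 0.046), a 3.82-fold fall from 385 ± 3.25 CPM in CON (edgeR adjusted p = 5.52e-14). For these other targets, the values argue against a general rise of weakly expressed genes as the whole cause. Their median of 0.79 lay at percentile 100 of 10000 random lists matched on mean expression, whose highest median was 0.69. The random lists drew genes singly, while REST targets may move together. The list's camera call in limma was lost at adjusted p = 0.182 with an estimated correlation. Syp, Scg3 and Drd2 were left out of the list, so the comparison cannot decide for them. These data do not measure REST protein or its binding. Doxycycline and the knockdown cannot be told apart here, because all KD libraries had both.

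For the fall of the ATF4 list, the choice between TMM and size-only scaling is not the whole cause. It moved the median of all genes by 0.229 and that of the list from -1.95 to -1.72. A shift of all genes by that amount could not have removed the fall, so this is no test of other scaling errors. Trends with GC content and transcript length are not the whole cause either, as the list median was -2.01 after both were removed. Across all genes these trends were weak, with Spearman correlations of 0.111 for GC content and 0.058 for length with the log2 fold change. Endoplasmic reticulum stress in the CON cultures would leave the unfolded protein response list lower in KD. Its median was 0.35, with 18 genes higher and 3 lower (exact binomial p = 0.00149, two-sided, across genes, which are not independent replicates). These are the values of the fixed list given above, known before this question was put, so the binomial p describes them and is no independent test. The list's camera call in limma was lost, at adjusted p = 0.109 with an estimated correlation. Hspa5, the BiP gene, rose 1.67-fold while Herpud1 fell 4.43-fold, so the values argue against such stress for most of the list and not for each gene. Atf4 mRNA fell 4.23-fold from 388 ± 2.49 to 91.7 ± 1.95 CPM, and a lower supply of this factor may contribute. Atf4 is itself a member of the list, so its fall is part of the pattern, and ATF4 protein was not measured. Amino acid supply and culture density stay open, as neither was measured. Doxycycline itself stays open too, as all KD libraries and no CON library received it.

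The rise of the Zscan4 genes is not explained by a redistribution of reads among copies, since their summed count rose by 1.26 on the log2 scale (SE 0.078), from 714, 644 and 661 counts in CON to 1825, 2064 and 1798 in KD. Which copy rose stays open. A general rise of weakly expressed genes may still contribute and cannot be told apart from a change of these genes. Their median of 1.15 lay at percentile 98.94 of matched random lists, whose median of 0.2 was itself above 0. The random lists drew genes singly, while the Zscan4 copies may share reads and move together, so this percentile may overstate how rare their median is. A larger share of 2C-like cells would give the same sum as more Zscan4 RNA per cell, and bulk RNA cannot separate them.

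Of the 10 splits of the 6 libraries into groups of 3, only the real one (1 split) called as many genes, 11344, and the highest of the others called 0. The real split called 13 lists with camera at the preset correlation, and 3 splits called as many, the real one included, the highest of the others being 13. The other splits called from 9 to 13 lists. Each of them mixes CON and KD libraries unequally, so part of the real difference remains between its groups. The rest of that difference adds to the spread within them. They are thus not groupings without a difference, and they cannot show how often unchanged genes or lists are called. The 10 splits are too few for a share under 0.05. With an estimated correlation the real split called 6 lists and the highest of the others 0. The 0 genes and 0 lists of the other splits therefore do not test the calls of the real one.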
